A study of Homo sapiens with 3 samples.

How the data were processed

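Total RNA from SW480 cells was sequenced in 3 libraries, 2 from cells transduced with control shRNA and 1 from cells transduced with an shRNA against RBMS1. The labels do not say whether both control libraries carry the same hairpin. Per the labels' protocols, RNA was extracted 48 hours after transduction with a column kit and DNase I, ribosomal RNA was removed with Ribo-Zero Gold, and libraries were made with a ScriptSeq kit and read on a NextSeq 500. Samples were grouped by the shRNA named in the labels.

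The submitters' processing notes name STAR 2.5, Cufflinks, Cuffdiff and the hg38 genome build. They give no roles, order or settings for these tools, and filters on low levels are not given in the sources used here. The values used here are log2 fold changes per RefSeq transcript that the authors computed, shRBMS1 over shControl, in 1 deposited table of 20104 transcripts. Levels and counts per library were not analysed here, so the depth behind each value is unknown and no error, interval or floor was computed. With no level per gene, random lists were not matched on mean expression.

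The file header names the column as a log fold change without its base or direction. Base 2 was taken from the spacing of repeated values, since 20 transcripts lay 1 away, within 1.5e-05, from a value that occurs at least 3 times. With the same tolerance, distances of ln 2 and log10 of 2 gave 4 and 5 transcripts, and 200 random distances gave a median of 3 and at most 11. The direction was taken from RBMS1, which lay below 0. If the direction were the other way, every sign in the text would turn.

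Gene names came from a RefSeq gene table of GRCh38.p14, the same assembly as hg38, which matched 19818 of the 20104 transcripts (98.6%). The other 286 transcripts were left out of values per gene. A gene's value was the median of its transcripts in the table, which gave 12582 genes, 11487 of them protein-coding and 1095 with non-coding transcripts alone. Of these genes, 7985 had 1 measured transcript and 4597 had more. Transcript length, GC content, coding sequence and 3′ UTR sequence came from GENCODE 29 through its RefSeq links, and 11180 genes had a 3′ UTR.

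Genes at or beyond 1 on the log2 scale in either direction were counted without a test. For each of 27 gene lists, the list's median was placed as a percentile among the medians of 10000 random lists of the same size drawn from the other measured genes. Lists with fewer than 3 measured members were left out. A list was called below or above when its median lay outside the central 95% of the random lists. These percentiles describe these libraries, and no p-value across genes was computed. The lists, grouped by theme, covered ribosomal proteins, ribosome biogenesis and MYC targets, splicing factors, replication-dependent histones, and G1/S and G2/M genes. They covered cholesterol synthesis, hypoxia and glycolysis, the mitochondrial respiratory chain, ER chaperones, and the ATF4, p53, NRF2, interferon and inflammatory responses. They also covered immediate-early genes, Wnt, YAP and TGF-beta targets, epithelial junction genes, mesenchymal genes, integrins and matrix adhesion, colon differentiation genes, and AU-rich element and stability factors. Markers of leukocytes, fibroblasts and endothelial cells stood for cell types that a pure line should lack.

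The 3′ UTR site test took the median of genes whose 3′ UTR holds ATATA minus that of genes without it. This difference was set against 10000 permutations of the site labels within 10 bins of 3′ UTR length and 5 bins of A+T content. The other 9 sequences of 5 bases made of 3 A and 2 T served as controls.

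The lists, tests, thresholds, other settings to be tried and the rule for named genes were fixed before the data were examined. The rule named RBMS1, RBMS2, RBMS3, AKAP12 and SDCBP, the 10 highest and 10 lowest protein-coding genes, and the highest and lowest member of each list. Lists outside the central 95% of the random lists had 2 members named at each end. Alternatives were other thresholds, other ways to take 1 value per gene, centring on the median of all genes, protein-coding genes alone, means of lists, random lists matched on transcript length and GC content in 10 bins each, and other sites, regions and matchings for the site test.

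The list and site tests were tested on simulated data made by adding known shifts to the real values. Over 12582 genes, lists of 25 genes with no shift were called below in 2% and above in 3% of 200 simulations. With a shift of −0.15 the call was made in 35.5%, and with −0.30 in 91.5%. For the site test over 11180 genes with 40 simulations each, no shift gave 2.5% below and 5% above, a shift of −0.02 gave 45% below, and −0.05 gave 100%. The site simulations kept the real site labels and bins and shuffled values within bins. The list simulations shuffled values over all genes, which removes any tendency of a list's members to vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.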

Results

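Total RNA was sequenced from SW480 cells, an established human colon adenocarcinoma line, after transduction with a short hairpin RNA (shRNA) against RBMS1 or with control shRNA. RBMS1 is an RNA-binding protein that recognises A+U-rich sequence, AUAUA among it. There were 2 control libraries and 1 RBMS1 knockdown library, collected 48 hours after transduction, and whether both controls carry the same hairpin is not given in the sources used here. The comparison asks which transcripts differ in level when RBMS1 is reduced. With 1 knockdown library, the difference has no replicate check, and no p-value across genes is given. All values per transcript are log2 fold changes from the authors' deposited table, knockdown over control, and a gene's value is the median of its transcripts there. The deposited table itself lists transcripts alone, so a gene's value credited to it below is this median, computed here. The sequencing depth behind them is unknown.

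The direction of the ratio was set so that RBMS1, the targeted gene, lies lower in the knockdown, so its sign is fixed by that choice and does not check the labels, whereas its size was measured. The authors' deposited table put the gene, on chromosome 2 at 160272151 to 160493807 (hg38), at −1.49, which is 35.6% of control. Its transcript NM_002897 was at 39.1% of control in the authors' deposited table and NM_016836 at 32.5%. The paralogue RBMS2, on chromosome 12 at 56520405 to 56596193, was also lower, at −0.57 or 67.5% of control in the authors' deposited table. A value for RBMS3 was not analysed here.

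AKAP12 and SDCBP, recalled as RBMS1-stabilised transcripts from the study's published work, both lay lower in the knockdown. AKAP12, a scaffold of protein kinase A on chromosome 6 at 151239967 to 151358559, was at −0.76 or 59.0% of control in the authors' deposited table. SDCBP, which encodes the adaptor syntenin and lies on chromosome 8 at 58553261 to 58582858, was at −0.58 or 67.0% of control there, with −0.40 and −0.75 for its transcripts in the authors' deposited table. These values stood at percentiles 6.76 and 10.6 of all genes. The annotated 3′ UTR holds 2 ATATA sites in AKAP12, 1 in SDCBP, 10 in RBMS2 and 1 in RBMS1. Such sites are common: of 11180 genes with a 3′ UTR, 6571 hold at least 1 and 4892 at least 2. AKAP12 and SDCBP were taken from the study's own published work, so their direction is not independent evidence.

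Most genes differed little between the arms. The median over 12582 genes was 0.01 with quartiles of −0.25 and 0.23, and 9671 genes (76.9%) lay within 0.5 of 0. No transcript lay beyond 10 in either direction while 109 lay between 9 and 10, so the order of the extreme genes holds only within that limit of the table. At the ends, 497 genes were higher by at least 1 on the log2 scale and 498 were lower by at least 1. By the median of transcripts in the authors' deposited table, the mitochondrial carrier SLC25A45 was highest among protein-coding genes, at 9.85. Then came ZNF610 at 9.80, the kinase CDK18 at 9.66, the tubulin carboxypeptidase VASH2 at 9.62 and the small GTPase RAB30 at 9.09 in the authors' deposited table. Single transcripts of other genes stood higher, such as one of ELAVL2 at 9.96 in the authors' deposited table. Next by this median in the authors' deposited table came TOX2 at 8.88, MPP3 at 8.27, PGAP3 at 8.19, NRGN at 7.98 and HDX at 7.46. Lowest by this median in the authors' deposited table were the protein kinase C isoform PRKCQ at −9.68, the homeobox gene PBX3 at −9.29, JAKMIP1 at −8.98, ANGPTL4, an inhibitor of lipoprotein lipase, at −8.94, and DPYSL5 at −8.52. By the same median in the authors' deposited table, the pro-apoptotic gene BMF followed at −7.94, ZBTB48 at −7.66, the splicing regulator PTBP2 at −7.58, the monocarboxylate transporter SLC16A5 at −6.54 and MARF1 at −6.36. PBX3, DPYSL5 and PTBP2 each have 3 transcripts in the authors' deposited table, of which the highest were at 0.01, 1.22 and 0.75. For PBX3 the transcript at 0.01 is the only coding one there, and the −9.29 comes from a non-coding transcript. The −7.58 of PTBP2 is also that of a non-coding transcript, and its coding one was at −9.42 in the authors' deposited table. The 10 highest genes each rest on 1 measured transcript, as do the 10 lowest apart from PBX3, DPYSL5 and PTBP2. Values this large have no level beside them, so a level near 0 in 1 arm cannot be told apart from a large change. Of the 4597 genes with several transcripts, 2266 (49.3%) had transcripts more than 1 apart. Of the 97 genes besides RBMS1 that the rule for named genes chose, 29 moved by more than 0.58 or changed sign with another way to take 1 value per gene. All 29 have several transcripts, and genes with 1 could not move in this way.

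Of the 25 gene lists with at least 3 measured members, 10 lay below the central 95% of random lists and 3 lay above. Lists of randomly drawn genes would put 1.25 outside. Members of a real list can vary together between libraries, so more lists than that can lie outside without an effect of RBMS1. The lower lists were epithelial junction genes, integrins and matrix adhesion, immediate-early genes, targets of Wnt, YAP and TGF-beta, interferon-stimulated genes, ATF4 stress genes, hypoxia and glycolysis genes, and AU-rich element and stability factors. The higher lists held genes of ribosomes, ribosome biogenesis and the respiratory chain. Cell cycle, histone, p53, NRF2, chaperone and cholesterol lists lay inside. A gene's value also ran with the composition of its transcript: Spearman's rho across genes, which are not independent replicates, was −0.173 with GC content and −0.138 with length. Of 10 equal bins by GC content, the lowest had a median of 0.13, the highest but 1 a median of −0.09 and the highest −0.03. Of 10 bins by length the shortest and longest stood at 0.08 and −0.11.

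**Figure D1:**
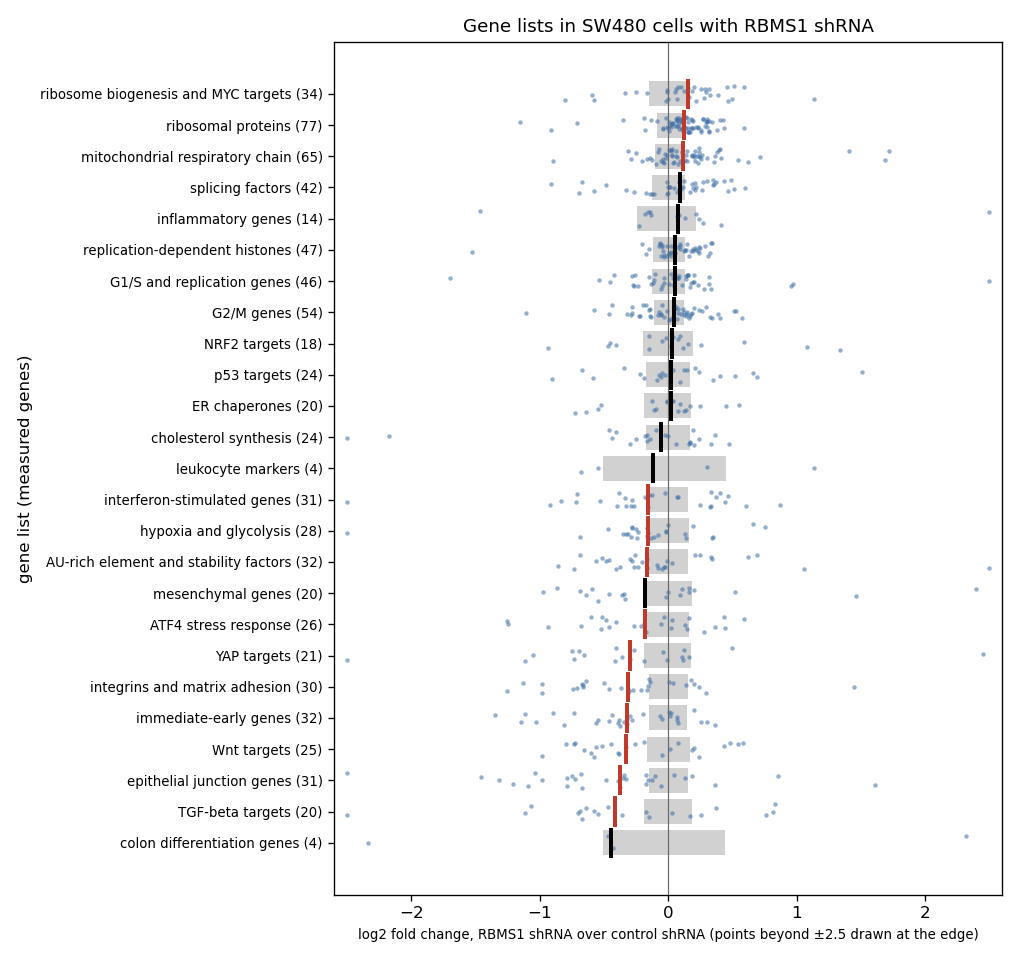
Log2 fold change, RBMS1 shRNA over control shRNA, of each measured member (points) of 25 gene lists, with the list's median as a vertical bar, red where it lies outside the grey band that holds the central 95% of 10000 random lists. The 9 genes beyond 2.5 in either direction are drawn at the edge, and medians run from −0.45 for colon differentiation genes, with 4 members inside their band, to 0.16 for ribosome biogenesis and MYC targets.

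Epithelial junction genes, which encode adherens and tight junction parts and their regulators, had the lowest percentile of all lists. Their median was −0.37, 77.2% of control, below all 10000 random lists, and 25 of the 31 measured genes lay below 0. Among them 6 were lower by at least 1 and 1 was higher by at least 1. By the median of transcripts in the authors' deposited table, AP1M2, a clathrin adaptor subunit of epithelial cells, was at −3.71 and the membrane protein MAL2 at −1.46. Against these stood 1.61 for the epithelial transcription factor EHF and 0.85 for the tight junction gene TJP3 in the authors' deposited table. The transcripts of AP1M2 went both ways in the authors' deposited table, at −9.73 and 2.32. The list stayed below the random lists under every alternative tried.

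Integrins and matrix adhesion genes had a median of −0.31 at percentile 0.02, with 22 of 30 below 0, 2 lower by at least 1 and 1 higher by at least 1. In the authors' deposited table, the integrin ITGB8 was at −1.26 and the laminin chain LAMB3 at −1.13, while the integrin activator FERMT2 was at 1.44 and the focal adhesion gene ZYX at 0.29. The transcripts of FERMT2 were at 0.18 and 2.71 in the authors' deposited table. Mesenchymal genes, of which 20 of 33 were measured, had a median of −0.18 at percentile 3.04, inside the random lists. Against lists matched on transcript length and GC content they lay below, at percentile 0.47. Only 19 of the 20 entered that setting, and their median was −0.34, while the random median moved from 0.01 to −0.04. That call therefore cannot be credited to the matching alone. With the longest or least changed transcript of each gene mesenchymal genes lay at 0.21 and 0.05, also with a median of −0.34. Without genes that sit in more than 1 list, a setting chosen after seeing the data, their median had the other sign, 0.0352 at percentile 57.9. The cadherin CDH11 was highest of them at 2.39 in the authors' deposited table, and fibronectin, FN1, lowest at −0.97. The integrin list returned to the band when its mean was used, at percentile 2.60, and when only genes with 1 measured transcript were kept, at 3.14.

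Immediate-early genes, the first to respond to serum and growth factors, had a median of −0.32 at percentile 0.01, with 22 of 32 below 0, 4 lower by at least 1 and 0 higher by at least 1. The authors' deposited table had the transcription factors KLF2 at −1.35 and EGR1 at −1.15, and at the other end ATF3 at 0.37 and the phosphatase DUSP4 at 0.31. For ATF3, transcripts ran from −7.53 to 2.11 in the authors' deposited table. This list also stayed below the random lists under every alternative tried.

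Wnt targets had a median of −0.33 at percentile 0.08, with 16 of 25 below 0 and none beyond 1 in either direction. CD44, a hyaluronan receptor, was at −0.99 and the transcription factor SOX9 at −0.79 in the authors' deposited table, against 0.58 for FGF9 and 0.55 for TNFRSF19. The transcripts of CD44 ran from −3.40 to −0.10 in the authors' deposited table. TGF-beta targets had a median of −0.41 at percentile 0.02, with 13 of 20 below 0 and 3 lower by at least 1. Among them the authors' deposited table had LTBP3, a binding protein of latent TGF-beta, at −4.62 and the matricellular gene CCN2 at −1.12, with the inhibitory SMAD6 at 0.84 and ID1 at 0.82. YAP targets had a median of −0.29 at percentile 0.28, with 15 of 21 below 0, 3 lower by at least 1 and 1 higher by at least 1. The ectonucleotidase NT5E was lowest at −4.45 in the authors' deposited table, CCN2 followed, and AMOTL1 at 2.46 and TGFB2 at 0.50 were highest. LTBP3 and NT5E each rest on transcripts far apart in the authors' deposited table, −8.69 and −0.55 for the one and −8.88 and −0.01 for the other. TGF-beta targets moved to percentile 6.42 without genes that sit in more than 1 list, Wnt targets to 22.5 with the least changed transcript of each gene, and YAP targets to 2.54 with the mean.

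The remaining lower lists stood closer to the edge of the random lists. Interferon-stimulated genes had a median of −0.15 at percentile 2.21, with 19 of 31 below 0, and the transcripts of IRF7, a transcription factor of the interferon response, were at −9.81 and 2.76 in the authors' deposited table. IRF7 as a gene was at −3.53 and IFI35 at −0.92 in the authors' deposited table, against 0.87 for IFI27 and 0.61 for IFITM1. Genes of the ATF4 stress response had a median of −0.18 at percentile 1.66, with 16 of 26 below 0. There the authors' deposited table had the serine hydroxymethyltransferase SHMT2 at −1.25 and the glutathione-degrading CHAC1 at −1.25, with CARS1 at 0.59 and VLDLR at 0.44. Hypoxia and glycolysis genes had a median of −0.16 at percentile 2.17, with 21 of 28 below 0. Besides ANGPTL4, NDRG1 was low at −0.69 in the authors' deposited table, while the angiogenic factor VEGFA was at 0.75 and the aldolase ALDOC at 0.66. AU-rich element and stability factors, which bind or deadenylate mRNA, had a median of −0.16 at percentile 1.70, with 23 of 32 below 0. The deadenylase subunit CNOT3 was at −0.85 and ZFP36L2 at −0.74 in the authors' deposited table, against 2.90 for CPEB4 and 1.06 for AUH. Transcripts of CPEB4 stood at −2.10 and 7.91 in the authors' deposited table, and those of SHMT2 ran from −9.91 to 0.24. Those of CARS1 ran from −0.32 to 1.47 in the authors' deposited table, and those of VLDLR stood at −0.43 and 1.32. Matched on transcript length and GC content, the ATF4 list moved to percentile 5.01 and the hypoxia list to 3.23, both inside. The interferon list moved to 2.65 and the stability list to 5.10 when a gene's value was the mean of its transcripts.

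Ribosome biogenesis and MYC targets had a median of 0.16 at percentile 98.2, with 25 of 34 above 0. The nucleolar gene NOP16 was at 1.14 and GNL3 at 0.59 in the authors' deposited table, and the spermidine synthase SRM at −0.80 and the pyrimidine enzyme CAD at −0.59. Transcripts of NOP16 ran from 0.01 to 1.22 in the authors' deposited table. Ribosomal proteins had a median of 0.12 at percentile 99.1, with 65 of 77 above 0. In the authors' deposited table RPL39 was at 0.59 and RPL7 at 0.43, whereas RPLP1 was at −1.15 and RPS16 at −0.92. How reads were divided between ribosomal protein genes and their processed copies is not given in the sources used here. Genes of the mitochondrial respiratory chain had a median of 0.11 at percentile 97.6, with 47 of 65 above 0. The ATP synthase subunit ATP5PD was at 1.72 and the complex I subunit NDUFV1 at 1.69 in the authors' deposited table, and SDHC at −0.90 and NDUFA2 at −0.31. Both high values rest on transcripts apart in the authors' deposited table, 0.06 and 3.38 for ATP5PD and −0.15 and 3.53 for NDUFV1. Against random lists matched on transcript length and GC content, ribosomal proteins moved to percentile 90.4 and the respiratory chain to 87.5, both inside. Ribosome biogenesis stayed above at 99.3 in that matching, and moved inside, to 67.2, with the least changed transcript of each gene.

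Lists of proliferation lay inside the random lists. G1/S and replication genes had a median of 0.05 at percentile 72.9 and G2/M genes 0.05 at 72.5. MCM3, a subunit of the replicative helicase, was at 4.17 and DTL at −1.70 in the authors' deposited table, and among G2/M genes the kinesins KIF14 and KIF23 stood at 0.58 and −1.11. The value of MCM3 joins transcripts at 0.09 and 8.25 in the authors' deposited table, and that of DTL −4.71 and 1.31. Transcripts of KIF14 stood at −0.41 and 1.56 in the authors' deposited table, and those of KIF23 at −2.24 and 0.02. Replication-dependent histones, near-identical copies among which reads are hard to divide, had a median of 0.05 at percentile 75.7, with H4C2 at 0.34 and H3C6 at −1.53 in the authors' deposited table. Splicing factors had a median of 0.09 at percentile 89.6, with SRSF8 at 0.60 and HNRNPH3 at −0.91 in the authors' deposited table, and of −0.00549 among genes with 1 measured transcript.

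Stress and metabolic lists inside the random lists were p53 targets, with a median of 0.02 at percentile 56.4, NRF2 targets with 0.03 at 57.2, ER chaperones with 0.02 at 55.3, and cholesterol synthesis genes with −0.06 at 20.1. Small medians like these depend on the setting: ER chaperones had a mean of −0.04, and p53 targets a median of −0.08 at percentile 11.2 with the least changed transcript of each gene. The pro-apoptotic p53 target BBC3 was at 1.51 and ZMAT3 at −0.91 in the authors' deposited table, and the NRF2 targets TXN and SLC7A11 at 1.34 and −0.93. CRELD2 was at 0.55 and the chaperone HSPA5 at −0.73 in the authors' deposited table, and of the sterol enzymes SQLE was at 0.47 and FDFT1 at −4.01. Transcripts of FDFT1 stood at −8.28 and 0.25 in the authors' deposited table, those of BBC3 at −1.19 and 4.21, of ZMAT3 at −1.76 and −0.06 and of TXN at 0.36 and 2.32. Inflammatory genes, 14 of 33 measured, had a median of 0.08 at percentile 73.8, and of −0.03 at 35.3 with the mean of each gene's transcripts, with the chemokine CXCL10 at 2.57 and CSF2 at −1.47 in the authors' deposited table. Few colon differentiation genes were measured, 4 of 34, with a median of −0.45 at percentile 3.44, and CHGA was at 2.32 and the microvillus gene VIL1 at −2.33 in the authors' deposited table. Leukocyte markers, 4 of 18 measured, had a median of −0.12 at percentile 27.7 and a mean of 0.06, with LAPTM5 at 1.14 and LYZ at −0.68 in the authors' deposited table. Of the fibroblast and endothelial markers, 2 of 15 and 1 of 11 were measured, too few to place.

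Genes with the ATATA site in the 3′ UTR did not stand apart from genes matched on 3′ UTR length and A+T content. The median of the 6571 genes with a site was higher by 0.0196 than that of the 4609 genes without one, at percentile 22.5 of the matched permutations, whose median difference was 0.0236. The narrower site [GT]ATATA[GC], present in 2971 genes, lay at percentile 21.7, genes with at least 2 sites at 51.3, and the site in coding sequence at 92.1. TATATA, in 4491 genes, lay at 3.16, near the lower edge. Of the 9 control sequences, TAATA and AATAT lay lower than ATATA, at percentiles 9.97 and 15.9, and AAATT lay above the central 95%, at 99.8. Matched on 3′ UTR length alone the ATATA difference lay at percentile 100 and unmatched at 99.4, and values ran with 3′ UTR A+T content at a rho of 0.170 across genes.

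**Figure D2:**
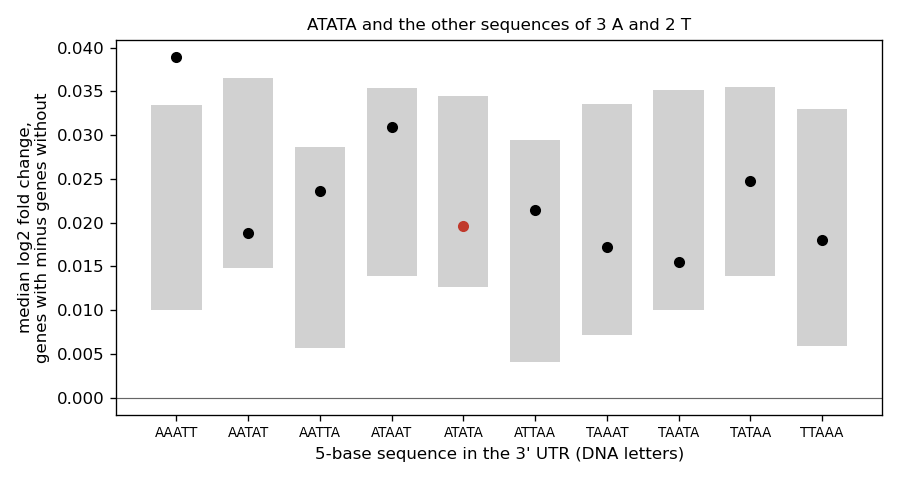
Difference in median log2 fold change between genes with and genes without each of the 10 sequences of 3 A and 2 T in the 3′ UTR (points, ATATA in red), with grey bands for the central 95% of 10000 permutations matched on 3′ UTR length and A+T content. ATATA, at 0.0196, lies inside its band, and AAATT alone lies outside.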

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

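Settings with 1-transcript genes, without genes that sit in more than 1 list and without genes that hold TTCAACC or TCAACCA were chosen after seeing the data. With 1 knockdown library and 1 value per transcript, no setting has a replicate error behind it, depth limits could not be read, and the causes of the changes below were not tested. No paired analysis was possible because the groups share only 1 replicate number and values per library were not analysed here. Filters and pseudocounts on FPKM and leaving out a control library were not run, since levels per library were not analysed here, and there were no values at 0 or infinite to keep. Of 223 list values under alternatives, 178 kept their call, 40 lost it and 5 gained one. All 5 were mesenchymal genes coming below, at −0.34 and percentile 0.21 with the longest transcript, 0.05 with the least changed transcript, 0.17 among genes with 1 measured transcript and 0.47 when matched, where 19 of the 20 members entered. Without genes that hold TTCAACC or TCAACCA they lay at −0.18 and 2.26. Of 386 values of 97 named genes besides RBMS1, 29 changed sign, 30 moved by more than 0.58 with the same sign, a limit set after the values were seen, and 327 stayed within it. These 29 and 30 values belong to 29 genes, all with several transcripts. For genes with 1 measured transcript only centring can change the value, by 0.01, so their values among the 327 were fixed in advance. RBMS1 stayed between −1.50 and −1.36 in every setting, and AKAP12 and SDCBP stayed below 0. The sign of these last genes was fixed in advance, since AKAP12 has 1 transcript and those of SDCBP are at −0.40 and −0.75.

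Counts followed the threshold: 1051 genes were higher and 1325 lower at 0.58, and 136 and 160 at 2. Counting every transcript on its own gave 1662 higher and 1581 lower, and the least changed transcript of each gene 331 lower. Genes with 1 measured transcript gave 264 and 258. Fewer genes enter there, and the share at or beyond 1 was also smaller, 6.54% against 10.3% of genes with several transcripts.

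With the mean of each list's members, the lists below numbered 4 and those above 0. Lost calls were ATF4 at −0.21, AU-rich element and stability factors at −0.0251, Wnt at −0.22, YAP at −0.38, integrins at −0.31, interferon at −0.19, respiratory chain at 0.17, ribosomal proteins at 0.10 and ribosome biogenesis at 0.13. With the mean of a gene's transcripts, 1 list stayed above, and stability factors at −0.12, hypoxia at −0.16, interferon at −0.15, respiratory chain at 0.11 and ribosome biogenesis at 0.14 lost theirs. The longest transcript left 1 list above and ended the calls of ATF4 at −0.0564, interferon at −0.15, respiratory chain at 0.0741 and ribosome biogenesis at 0.0674. The least changed transcript left 1 above and ended those of ATF4 at −0.12, stability factors at −0.10, Wnt at −0.0447, interferon at −0.0817, respiratory chain at 0.0568 and ribosome biogenesis at 0.0296.

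Random lists matched on transcript length and GC content left 1 list above and took ATF4 at −0.17, hypoxia at −0.16, respiratory chain at 0.11 and ribosomal proteins at 0.12 inside. Genes with 1 measured transcript left 1 above and took hypoxia at −0.16, integrins at −0.19, interferon at −0.16, respiratory chain at 0.0741 and ribosome biogenesis at 0.0761 inside. Without genes that sit in more than 1 list, 6 lists stayed below, and ATF4 at −0.17, stability factors at −0.13, TGF-beta at −0.17 and hypoxia at −0.16 came inside. Without genes that hold TTCAACC or TCAACCA in the 3′ UTR, 1 list stayed above, and ATF4 at −0.11, respiratory chain at 0.11 and ribosome biogenesis at 0.16 came inside. Epithelial junction and immediate-early genes kept their call in all of these settings. Medians of lists inside the random lists had the other sign 12 times, with no call in any. Mesenchymal genes were at 0.0352, at percentile 57.9, without genes that sit in more than 1 list. With the mean of members ER chaperones were at −0.0421 and leukocyte markers at 0.0553, and with the mean of transcripts p53 targets at −0.00422 and inflammatory genes at −0.0332. The longest transcript put p53 targets at −0.0496 and ER chaperones at −0.0381, and the least changed transcript put them at −0.0796 and −0.0381. Among genes with 1 measured transcript, p53 targets were at −0.0496, ER chaperones at −0.0102 and splicing factors at −0.00549. The ATATA difference of 0.0196 lay above its band when matched on 3′ UTR length alone or unmatched.

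Signs turned where transcripts of a gene disagree in the authors' deposited table, from which the values here come. The mean of transcripts put ATF3 at −1.68 and GNL3 at −0.12. Both the longest and the least changed transcript put AP1M2 at 2.32, AUH at −0.10, BBC3 at −1.19, CAD at 0.0212, DPYSL5 at 1.22, FDFT1 at 0.25, IRF7 at 2.76, KIF14 at −0.41, NDUFV1 at −0.15 and PBX3 at 0.0117. The longest transcript put SHMT2 at 0.24. The least changed transcript put CARS1 at −0.32, CPEB4 at −2.10, DTL at 1.31, KIF23 at 0.0206, PTBP2 at 0.75 and VLDLR at −0.43. With the sign kept, the least changed transcript in the authors' deposited table put NT5E at −0.0126, LTBP3 at −0.55, MCM3 at 0.0913, ATP5PD at 0.0568, FERMT2 at 0.18, NOP16 at 0.0116, SHMT2 at −0.0387, TXN at 0.36, EHF at 0.71, CD44 at −0.10 and ZMAT3 at −0.0578.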

Other observations

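Tests chosen only after the result was seen were the reading of each of the 3 higher lists by itself against matched lists (the matching was fixed before), the sister transcripts, the transcripts without a measured sister, genes with 1 annotated transcript, the base composition of the site, the settings with 1-transcript genes, without shared genes and without site genes, the gene families and the sequence scan with its follow-up.

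Among 19 gene families picked by symbol after the data had been examined, keratins stood lowest. The 16 measured keratin genes, which form the intermediate filaments of epithelia, had a median of −0.65, below all 10000 random lists, and 13 lay below 0. In the authors' deposited table KRT7 was at −0.97 and KRT17 at −0.91, each from 1 transcript. KRT18 was at −1.09 from transcripts at −2.17 and −0.0154, and KRT8 at 0.05 from transcripts between −0.07 and 1.82, in the authors' deposited table. Matched on transcript length and GC content, keratins lay at percentile 0.01. Host genes of small nucleolar RNAs (SNHG genes) had a median of 0.25 at percentile 99.7, with 15 of 21 above 0, but at 93.8, inside the random lists, among non-coding genes alone, whose median was 0.10; no matching on length and GC content was made for them. They include SNHG1 at 0.46 and SNHG3 at 0.66 in the authors' deposited table. Protein-coding zinc finger genes named ZNF, 398 in number, had a median of 0.07 at percentile 99.7, and 98.7 when matched. Centring on the median of all genes shifts each of these values by 0.01 and turns no direction.

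Genes whose 3′ UTR holds TTCAACC lay lowest among 15564 tested sequences of 7 bases, with a standardised mean rank of −7.17, then came the overlapping TCAACCA at −6.48 and CCCCCCA, which is not in RBMS1, at −5.48, and the highest of all was 5.22. A candidate explanation is a seed-driven off-target effect of the RBMS1 shRNA. The lowest sequence (rank 1) occurs in RBMS1, in coding sequence at bases 1636 to 1642 of a transcript of 4273 bases. So do 21.2% of all sequences tested. Of the 25 lowest, 11 occur in RBMS1, but most of these are C-rich, such as CCCTCCC and CCACCCC, and lack the CAAC of TTCAACC. That count therefore does not bear on a seed of TTCAACC. In 20 random splits of the genes into 2 equal parts TTCAACC was lowest in 24 of 40 parts and TCAACCA in 7, and in the parts not used to find TTCAACC, which overlap between splits, the median differences to matched lists were −0.192 for the 8-base match TTCAACCA, −0.0652 for 7 bases and −0.0381 for 6, the order this hypothesis predicts. Against base composition, the other 209 sequences made of the same letters had a median rank of −0.35, and against division of reads between transcripts of 1 gene, the difference was −0.15 among genes with 1 measured transcript, at percentile 0, and −0.10 among genes with 1 annotated transcript, at 0.02, while among genes with several measured transcripts TTCAACC stood only at rank 275. The genes with 1 measured or annotated transcript were part of the scan that found TTCAACC, so these percentiles are not independent of it. Genes with a match in coding sequence alone also lay lower, by differences of −0.0877, −0.0708 and −0.0324 for 8, 7 and 6 bases, AKAP12 and SDCBP hold no 3′ UTR match and RBMS2 a 6-base one, and since the guide sequence was not used here, other small RNAs with this seed stay open.

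For the 10 lower and 3 higher gene lists, GC content and length of transcripts were argued against as the whole cause of the lower side, where 8 of the 10 lists stayed below matched random lists. On the higher side, ribosomal proteins (percentile 90.4) and the respiratory chain (87.5) moved inside as GC content and length would predict, and ribosome biogenesis, 1 of the 3, stayed above at 99.3. Without genes shared between lists 6 of the 10 stayed below, among genes with 1 measured transcript 7 did, and without genes with a seed site in the 3′ UTR 9 did. In that last setting Wnt targets moved to a median of −0.19 at percentile 1.96. It kept genes with the shorter match or with matches in coding sequence alone, and it cannot remove indirect effects, so it does not exclude a seed effect. Against division of reads with transcripts not in the table, the 98 members of the lower lists with 1 annotated transcript had a median of −0.30, at percentile 0 of random lists of such genes. These members also helped to place the lists below, so that percentile is not independent of how the lists were picked. A difference between the single knockdown library and the 2 controls unrelated to RBMS1 was not tested and stays open, as do an effect of RBMS1, a seed-driven off-target effect of the shRNA and the level of expression, on which lists were not matched.

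Of the 20104 transcripts, 406 lay beyond 5 on the log2 scale, 280 of them below. Division of reads between transcripts of 1 gene is a candidate explanation: the 374 with a measured sister transcript had sisters at a median absolute change of 0.58, 266 of them under 1 and 8 beyond 5. Such values made up 3.16% of transcripts in genes with several transcripts and 0.326% in genes with 1. A level near 0 in 1 arm could also put a transcript beyond 5 beside little-changed sisters. The sister values cannot tell this apart from division of reads. For the 26 in genes with 1 measured transcript, a level near 0 in 1 arm cannot be told apart from a large change, because levels were not analysed here, and 6 more had no gene name.

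For genes with ATATA against other genes, the difference lay at percentile 22.5 of permutations matched on 3′ UTR length and A+T content, and 2 of the 9 control sequences of A+T-rich sequence in general lay as low. In simulated data a shift of −0.05 in site genes was called in 100% of simulations and one of −0.02 in 45%. Every site gene was given the same shift there, so these rates do not cover a change in a small part of the site genes, which stays open.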
